A study of Glycine max and Zea mays and Sorghum bicolor with 46 samples.

How the data were processed

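The series holds 46 samples, of which 16 Smar2C2 libraries of maize, sorghum, wheat and rice came with a processed file. The other 30 samples had no file and were not analysed here. Each file lists strand-specific genome positions with a count of tags, which the authors deposited as whole numbers without normalization, 1 file per library, per the file headers and the values. A further column marks each position as real, and all positions carried the same mark, so it was not used. The submitters' processing notes list cutadapt 2.8, UMI-tools 1.0.1, STAR 2.7.2 and R 4.0.0 with no role or order, and the builds B73 RefGen_v4 and IRGSP-1.0, which fit maize and rice. The build of sorghum and of wheat, the rule for reads with several matches, any filter and the use of molecular identifiers are not stated in the labels. Counts were therefore treated as tags, and intervals and floors cover counting error only. Coordinates are those of the files. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical. No replicate pair differed by less than sampling noise: the lowest chi-square per degree of freedom was 2.59, between the wheat root replicates.

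TSRs were built per species from positions with at least 3 tags in at least 2 of the 4 libraries, joined when within 20 bp on a strand. The count of a library is the sum of all its tags between the first and last position. A TSR is named by its most used base. Sequences of the mitochondrion and chloroplast were left out of the tests and of the library sizes, and tested in a separate fit. The sorghum and wheat files held no sequence named as an organelle, so no tags were left out there. Root was tested against shoot in each species alone with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, tissue as the only term) under R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Adjusted p-values are from this test unless limma 3.58.1 is named. Positive log2 fold changes mean higher in root. Levels are CPM with the SD of 2 libraries. The SE of an edgeR log2 fold change is its absolute value divided by the square root of the F statistic of the test. It is not a fitted standard error, and it can be smaller than counting error where a tissue had few tags.

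TSRs given by position follow a rule fixed with the design: per species the 3 with the largest absolute log2 fold change in each direction among those with adjusted p under 0.05, a mean log2 CPM of at least 5 and both root libraries beyond both shoot libraries, and the TSR with the highest mean CPM of each tissue. Windows, the start of rice chromosome 9 and the organelle TSRs were picked by their share of tags after the values were seen. Where a tissue had 1 to 3 tags, the ratio is given with an exact 95% interval. The tests of genes, of gene lists and of sequence around start sites in the design were not run, because no annotation or genome of these 4 species was given. The photosynthesis, nutrient uptake and other lists fixed for them have no result for that reason.

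Shape used TSRs with at least 50 tags in a library, thinned to 50 tags, and the width from the 10% to the 90% quantile of tags. The most used base and the mean tag position were compared in TSRs with at least 50 tags in all 4 libraries, the latter with limma on the mean of each library. Shares of sequence classes were read from sequence names. Upstream opposite-strand neighbours were set against 100 shuffles of strand labels. Groups of 2 libraries were compared with an exact two-sided permutation test.

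These terms describe the surroundings of a TSR. A start zone sums a chain of TSRs of a strand, each within 1000 bp of the next, so a zone can be longer than 1000 bp. An isolated TSR has a mean of at least 100 CPM and, within 500 bp on either side on its strand, under 0.1% of its own tags. Use of TSRs within a zone was tested with edgeR's diffSpliceDGE.

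Each test was run on simulated data with 200 changed TSRs. For the edgeR tests, counts were drawn from the means and dispersions of the real libraries, with the same dispersion of a TSR in both tissues. For the limma test, normal values were drawn with the real spread between replicates, and shifts were 4 SDs of that spread and at least 2 bp. The edgeR test recovered 12% of 2-fold and 73% of 4-fold changes in maize, and 5% and 49% in sorghum. In wheat it recovered 0% and 0%, and in rice 3% and 25%. Each fold was set in 100 TSRs, and there were 17, 10, 0 and 14 false calls in these species. The changed TSRs were a far smaller share than the TSRs called in the real data, which makes the adjustment stricter. These rates therefore do not give the power of the edgeR test on the real counts. The limma test of mean position recovered 17% of shifted TSRs in maize, 34% in sorghum, 44.5% in wheat and 33.5% in rice. The zone test recovered 93%, 87.5%, 0% and 87.5% of zones with a TSR changed 4-fold.

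Alternatives were DESeq2 1.42.0 size factors with its Wald test, library size alone, no filter, a filter of 1 CPM in 2 libraries, a minimum of 5 tags, joining at 10 or 50 bp, the replicate number as a block, each library left out in turn, thinning to the smallest total, organelles kept, other tag minimums, widths, shifts, distances and pseudocounts, and several added later. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.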

Results

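Smar2C2, a method that captures the 5′ ends of RNA and so places transcription start sites at single bases, was applied to shoots and roots of maize, sorghum, wheat and rice grown for 4 weeks under 16 h of light. Each tissue of each species had 2 replicate libraries, which makes 16 libraries in 8 groups. The deposited values are counts of tags per base and strand. The question each comparison addresses is which start sites a plant uses in root and in shoot. Maize libraries held 22147545 and 33783154 tags in shoot and 25608828 and 48572245 in root. Sorghum libraries held 44162397 and 26478066 tags in shoot and 41359323 and 64078770 in root. Wheat libraries held 25797092 and 29389762 tags in shoot and 32780658 and 26256409 in root. Rice libraries held 36622634 and 21913679 tags in shoot and 38702780 and 48592752 in root. Nearby start positions on one strand were joined into transcription start regions (TSRs), of which there were 490061 in maize, 709749 in sorghum, 480607 in wheat and 636416 in rice. Of these, 43991, 44752, 49147 and 39957 reached a mean of at least 1 CPM (tag counts scaled to the depth of the library). No annotation of these genomes was used here, so TSRs are given by position and no gene is named. On 18 of the 22 wheat sequences the last tag lay within 100000 bp of position 536870912, so wheat starts farther along are not covered.

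Root and shoot libraries of a species differed clearly in how much they used each start region, and replicates lay closer together than tissues in all 4 species. Across TSRs, the correlation of log2(CPM + 1) was 0.977 between the maize shoot replicates and 0.983 between the root replicates, against 0.789 to 0.813 between shoot and root. In sorghum the replicate pairs correlated at 0.972 and 0.983, and the pairs of root and shoot libraries at 0.805 to 0.808. In rice the replicate pairs correlated at 0.973 and 0.975, and root with shoot at 0.746 to 0.769. Wheat differed from this picture in 1 library: its root replicates correlated at 0.983 and its shoot replicates at 0.810, with 0.612 to 0.756 between tissues. The gap between within-tissue and between-tissue correlation was 0.211 in wheat, 0.368 without shoot replicate 2, and 0.123 without root replicate 1. Among TSRs with a mean of at least 10 CPM the tissues correlated far less, at 0.207 to 0.223 in maize, 0.198 to 0.212 in sorghum, 0.0444 to 0.110 in wheat and 0.173 to 0.242 in rice, and the gap was 0.764 to 0.785. The minimum is set on the mean over both tissues, which drops TSRs low in both and keeps those high in a single tissue. Such a selection itself lowers the correlation between tissues, so the drop cannot be read as a trait of abundant TSRs. All these correlations run across TSRs, which are not independent replicates.

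In maize, 49118 of 119492 tested TSRs differed between root and shoot, with 25113 higher in root and 24005 higher in shoot (edgeR quasi-likelihood test, adjusted p under 0.05). TSRs higher in shoot took 51.5% and 47.5% of the tags of the shoot libraries, and 13.1% and 13.7% of those of the root libraries. TSRs higher in root took 38.1% and 37.3% of root tags and 11% and 11.9% of shoot tags. The largest rise in root was at position 102052605 of chromosome 3 (plus strand), which averaged 118 ± 5.93 CPM in root and 0.0991 ± 0.0549 CPM in shoot (SD, n = 2 per tissue; log2 fold change 9.93, SE 0.26, adjusted p = 4.46e-18). The next largest rises were at position 145848009 of chromosome 3 (plus strand), with a log2 fold change of 9.74, and at position 44427554 of chromosome 8 (plus strand), with 9.66. On the shoot side, the TSR at position 6387822 of chromosome 3 (minus strand) averaged 115 ± 4.09 CPM in shoot and 0.0512 ± 0.0163 CPM in root (log2 fold change -11.29, SE 0.25, adjusted p = 3.62e-19). It was followed by position 104331051 of chromosome 9 (minus strand) at -10.55 and position 295876619 of chromosome 1 (plus strand) at -10.30. The most used TSR of the shoot lay at position 96365370 of chromosome 3 (plus strand), with 39588 ± 1457 CPM in shoot and 987 ± 33.5 CPM in root (log2 fold change -5.69, SE 0.09, adjusted p = 1.14e-21). The most used TSR of the root, at position 222780404 of chromosome 2 (plus strand), averaged 14527 ± 1902 CPM there and was higher still in shoot, at 32390 ± 13807 CPM (log2 fold change -1.53, SE 0.17, adjusted p = 2.01e-07; -0.97 without shoot replicate 1 and -2.02 without shoot replicate 2). It had 99.7% of its tags at a single base and 29 same-strand tags within 500 bp on either side. The shoot tags at position 145848009 all came from replicate 2, and its log2 fold change was 9.05 without shoot replicate 1. At position 102052605 it was 10.53 without shoot replicate 1 and 9.22 without shoot replicate 2, and at position 104331051 it was -11.74 without root replicate 1 and -9.49 without root replicate 2. With TSRs of a strand chained at gaps of at most 1000 bp and summed into start zones, the log2 fold change was 2.25 at position 102052605 and -3.41 at position 104331051. Scaled by library size alone, 65.3% of the called TSRs were higher in root instead of 51.1%, and the median log2 fold change moved by 0.35. With DESeq2 15240 TSRs were higher in root and 18828 higher in shoot, so that 44.7% were higher in root, and without root replicate 2 the share was 43.5%. In counts simulated from these libraries the test recovered 73% of TSRs changed 4-fold and 12% of those changed 2-fold.

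In sorghum, 54632 of 200619 tested TSRs differed between the tissues, 24789 higher in root and 29843 higher in shoot. The shoot-higher TSRs took 42.4% of the tags of each shoot library and 5.07% and 4.87% of root tags, and the root-higher TSRs took 25.1% and 22.7% of root tags and 5.93% and 6.28% of shoot tags. The largest rise in root, at position 63270377 of chromosome 4 (minus strand), ran from 0.125 ± 0.0160 CPM in shoot to 102 ± 5.05 CPM in root (log2 fold change 9.07, SE 0.30, adjusted p = 1.2e-10). A neighbouring TSR at position 63280768 of the same strand rose by 8.58 on the log2 scale, and one at position 60837190 of chromosome 6 (minus strand) by 8.65. The largest change toward shoot was at position 5882031 of chromosome 3 (minus strand), with 139.5 ± 5.30 CPM in shoot and 0.116 ± 0.0755 CPM in root (log2 fold change -10.86, SE 0.36, adjusted p = 1.2e-10). Position 3317188 of chromosome 3 and position 70603579 of chromosome 2, both on the plus strand, followed at -10.54 and -10.45. A single TSR at position 54133784 of chromosome 3 (minus strand) held the most tags of the shoot, 77742 ± 8166 CPM against 2607 ± 349 CPM in root (log2 fold change -5.43, SE 0.38, adjusted p = 6.24e-08), with 80 same-strand tags within 500 bp. The most used TSR of the root, at position 43407652 of chromosome 10 (minus strand), averaged 35635 ± 8390 CPM in root and 25027 ± 9611 CPM in shoot and did not pass the test (log2 fold change -0.05, SE 0.36, adjusted p = 0.944). Its log2 fold change turned to 0.51 with library size alone, 0.45 without shoot replicate 1, 0.12 without root replicate 1 and 0.0074 with the replicate number as a block, and it had 100 same-strand tags within 500 bp. In start zones the log2 fold change was 5.71 at position 63270377 and -6.84 at position 3317188. The latter was -11.31 without root replicate 2, and that at position 5882031 was -11.64 without root replicate 1 and -10.16 without root replicate 2. Scaled by library size alone, 71.6% of the called TSRs were higher in root instead of 45.4%, with the median log2 fold change moved by 0.55. Without root replicate 1 the test called 24347 TSRs, 6884 of them higher in root, or 28.3%. With DESeq2 12922 TSRs were higher in root and 22632 higher in shoot, which makes 36.3% higher in root.

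In wheat, 24657 of 128625 tested TSRs differed, 14902 higher in root and 9755 higher in shoot, and 99.7% of them differed by at least 4-fold. The TSRs called higher in shoot took 22% and 30.3% of the tags of the shoot libraries and 1.62% and 1.49% of root tags. Those called higher in root took 12.8% and 12.2% of root tags and 0.438% and 0.697% of shoot tags. The TSR at position 401992418 of chromosome 1B (minus strand) averaged 82.9 ± 5.28 CPM in root and had 1 tag in the shoot libraries, a ratio of 4596 with a 95% counting interval of 825 to 181582 (log2 fold change 11.33, SE 0.93, adjusted p = 0.0143). Position 7138383 of chromosome 6B (minus strand) and position 530034755 of chromosome 7D (plus strand) each had 2 tags in shoot, with ratios of 2333 (646 to 19272) and 2084 (577 to 17214). Toward shoot, the TSR at position 506480989 of chromosome 4B (plus strand) averaged 5832 ± 988 CPM in shoot and 2.45 ± 2.30 CPM in root (log2 fold change -11.89, SE 1.09, adjusted p = 0.0172), with 7 same-strand tags within 500 bp. Position 421421698 of chromosome 5D (plus strand) reached 174 ± 15.4 CPM in shoot and 0.0876 ± 0.0377 CPM in root, a log2 fold change of -11.53. Position 44352920 of chromosome 2B (minus strand) had -11.12, with 419 ± 298 CPM in shoot. A window of 100 kb from position 300000001 of chromosome 5B held 2.95% ± 0.469 of shoot tags and 0.00608% ± 0.000464 of root tags. Both tissues had their most used TSR at position 315223316 of chromosome 2B (minus strand), with 43095 ± 19229 CPM in shoot and 25663 ± 2565 CPM in root and 8 same-strand tags within 500 bp. That difference did not pass the test (log2 fold change -1.42, SE 0.40, adjusted p = 0.0712) but did without shoot replicate 1 (-0.70) or shoot replicate 2 (-1.03), and with the replicate number as a block or the pairing crossed (-1.30 each), over a range of adjusted p from 4.61e-94 to 0.996 across the alternatives. Its log2 fold change was -0.84 without root replicate 1 and -0.44 without root replicate 2. The log2 fold changes of the other TSRs given by position also moved with single libraries. That on chromosome 1B was 10.62 without shoot replicate 1, 14.23 without shoot replicate 2 and 12.09 without root replicate 2. That on chromosome 6B was 9.71, 14.25 and 11.22. On chromosome 7D it was 13.96 without shoot replicate 1 and 11.12 without root replicate 2. The few shoot tags of each of these TSRs came from a single library, shoot replicate 2 on 1B and 6B and shoot replicate 1 on 7D. On chromosome 4B it was -10.48 without root replicate 1 and -12.59 without root replicate 2. On chromosome 5D it was -10.72 without shoot replicate 2 and -10.52 without root replicate 1, and at position 44352920 it was -9.45 and -10.44. Of the calls, 60.4% were higher in root, against 51.8% with DESeq2, 68.5% with library size alone, 82.8% without root replicate 1 and 90.9% without root replicate 2. The number of wheat calls moved strongly with any single library left out: it rose without either shoot library and fell without either root library. Each such fit chose the TSRs to test anew, so its calls are not out of the 128625 above. The common dispersion was 0.275 in wheat and 0.0209 to 0.0274 in the other species, and the test recovered 0% of simulated 4-fold changes in wheat.

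In rice, 57587 of 198352 tested TSRs differed, with 39654 higher in shoot and 17933 higher in root. The shoot-higher TSRs took 51.3% and 48.6% of shoot tags and 11.9% and 13.8% of root tags. The root-higher TSRs took 11.1% and 11.2% of root tags and 1.79% and 1.84% of shoot tags. The largest rise in root was at position 432875 of chromosome 3 (minus strand), from 0.116 ± 0.0327 CPM in shoot to 113 ± 24.1 CPM in root (log2 fold change 9.0, SE 0.30, adjusted p = 1.73e-09). Position 6011652 of chromosome 4 and position 7788796 of chromosome 3, both on the plus strand, rose by 8.64 and 8.56 on the log2 scale. The latter had 7 tags in shoot replicate 1 and 0 in shoot replicate 2, and its log2 fold change was 7.74 without shoot replicate 2. The TSR at position 19281012 of chromosome 11 (minus strand) averaged 94.7 ± 32.6 CPM in shoot and had 2 tags in root, a ratio of 4309 with a 95% counting interval of 1192 to 35587 (log2 fold change -12.58, SE 0.47, adjusted p = 2.9e-09). Position 32423272 of chromosome 3 and position 722980 of chromosome 11, both on the plus strand, followed at -11.71 and -11.56, the latter -10.91 without root replicate 1 and -12.91 without root replicate 2. In start zones the log2 fold change was -6.94 at position 19281012 and 6.47 at position 432875. The most used TSR of the shoot, at position 9246641 of chromosome 8 (minus strand), held 78936 ± 1813 CPM in shoot and 2182 ± 542 CPM in root (log2 fold change -6.00, SE 0.24, adjusted p = 5.02e-09). The first 40 kb of chromosome 9 held 6.21% and 6.68% of the tags of the shoot libraries and 16.7% and 10.4% of those of the root libraries. The most used TSR of the root lay there and is named by position 8912 of the plus strand. It spanned 918 bp with 6.06% of its tags at that base, and had 607281 same-strand tags within 500 bp on either side. It averaged 30666 ± 12198 CPM in root and 12380 ± 575 CPM in shoot, and did not pass the test (log2 fold change 0.52, SE 0.26, adjusted p = 0.181). It passed without shoot replicate 1 (0.50), without root replicate 2 (0.98) and with library size alone (1.31), and its log2 fold change was -0.010 without root replicate 1. Across the alternatives its adjusted p ran from 1.33e-35 to 0.949. With library size alone 118607 TSRs were called, 76.6% of them higher in root instead of 31.1%, and the median log2 fold change moved by 0.82. With DESeq2 10399 TSRs, or 25.9%, were higher in root.

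**Figure D1:**
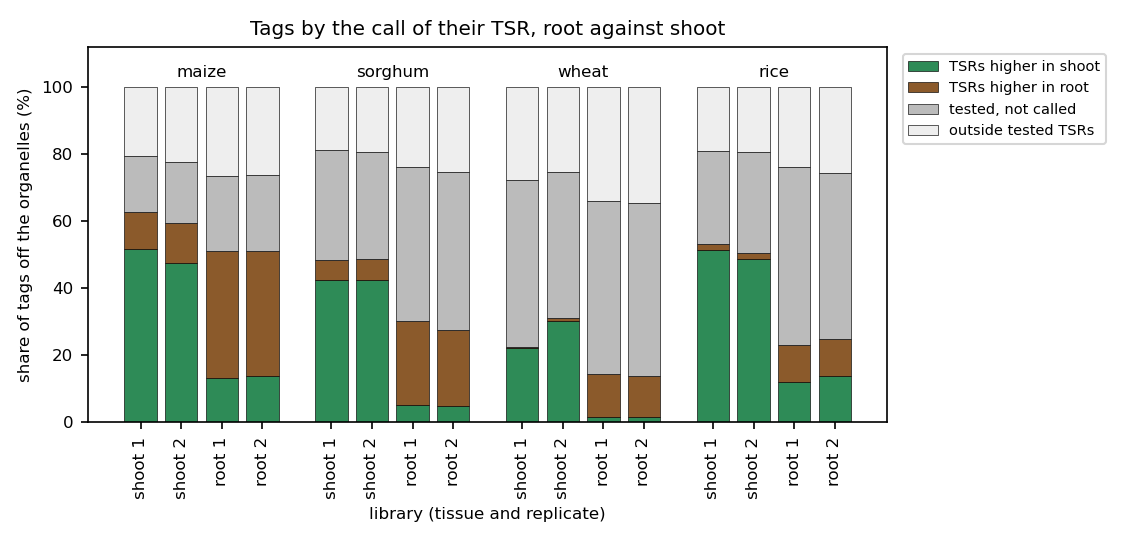
Share of the tags off the organelles in each of the 16 libraries (percent, stacked bars from 0), split by whether the TSR that holds them was higher in shoot, higher in root, tested but not called, or outside the tested TSRs. Shoot-higher TSRs took 22% to 51.5% of the tags of a shoot library and 1.49% to 13.8% of those of a root library. Sorghum and wheat had no sequence named as an organelle, so all their tags are included.

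Chloroplast transcription, which serves photosynthesis, was a shoot feature in both species whose sequences included the organelles. In maize 0.809% ± 0.0167 of shoot tags and 0.0335% ± 0.00224 of root tags lay on the chloroplast (SD, n = 2), a ratio of 24.2. In rice the shares were 1.42% ± 0.0159 and 0.0555% ± 0.0127, a ratio of 25.6. Tags of the mitochondrion, the site of respiration, went the other way. They made up 1.04% ± 0.0593 of maize shoot tags and 1.56% ± 0.0595 of root tags, and 0.768% ± 0.00488 of rice shoot tags and 1.71% ± 0.129 of root tags. Single libraries were measured closely: the 95% Wilson interval of the maize chloroplast share ran from 0.794% to 0.801% in shoot replicate 1 and from 0.0343% to 0.0358% in root replicate 1, counting error only. In a fit that kept the organelles, 410 of 417 maize chloroplast TSRs and 424 of 429 in rice were higher in shoot, with median log2 fold changes of -5.28 and -5.49. Of the mitochondrial TSRs, 271 of 809 in maize were higher in root and 52 higher in shoot, and in rice 236 of 1074 were higher in root and 80 higher in shoot. The other 486 and 758 were not called, and the median log2 fold changes were 0.60 and 0.41. This fit applies TMM scaling, which the shares of tags above do not. The maize TSR with the most chloroplast tags, at position 100895 (plus strand), averaged 1493 ± 21.6 CPM in shoot and 40.4 ± 0.766 CPM in root (edgeR log2 fold change -5.60, SE 0.13, adjusted p = 4.25e-25). In rice a TSR at chloroplast position 97048 (plus strand) held 45.6% of the chloroplast tags of the shoot and 39.8% of those of the root. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 (two-sided), and every one of these shares reached that value. Counted by positions instead of tags, the mitochondrial difference in maize was 0.0552 percentage points instead of 0.520 and in rice 0.237 instead of 0.942, and the chloroplast difference was -0.297 instead of -0.776 in maize and -0.267 instead of -1.36 in rice.

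**Figure D2:**
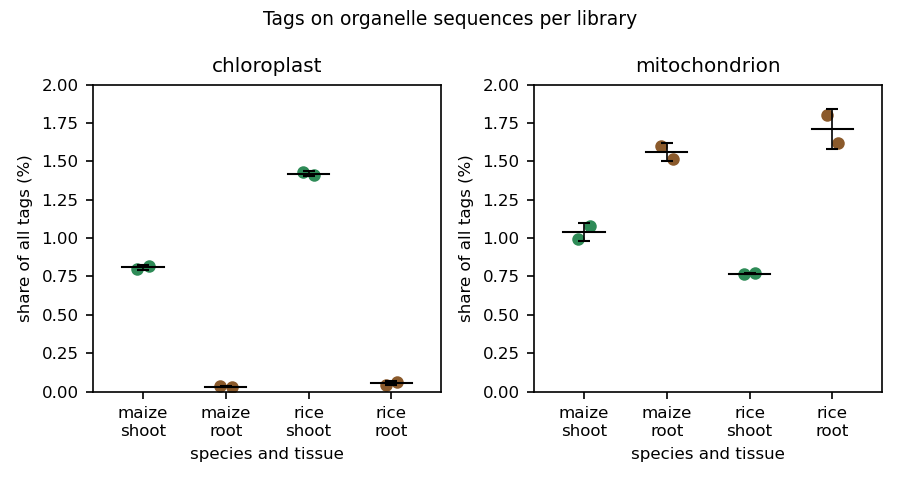
Share of all tags (percent) on the chloroplast and on the mitochondrion in each library of maize and rice. Points are libraries, lines are means of 2 and error bars are SD. The chloroplast share was 0.797% or more in every shoot library and 0.0645% or less in every root library.

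The A, B and D subgenomes of hexaploid wheat took similar shares of the covered tags, with small shifts between the tissues. Subgenome A held 27.3% ± 0.463 of shoot tags and 29.4% ± 0.640 of root tags (SD, n = 2). Subgenome B held 35.7% ± 1.97 in shoot and 32.2% ± 0.158 in root. Both root libraries lay beyond both shoot libraries in each, and the exact permutation p was 0.333 (two-sided), the lowest it can be. Subgenome D held 33.9% ± 2.08 and 34.5% ± 0.396, a difference within the spread between replicates. Counted by positions, the root minus shoot difference of subgenome A turned from 2.15 to -0.0260 percentage points, and that of subgenome B went from -3.49 to -0.275. Without shoot replicate 1 the difference of subgenome B was -2.09 percentage points. The 100 kb window of chromosome 5B given above held 2.95% of shoot tags and 0.00608% of root tags, a change close in size to that of the whole subgenome. Starts beyond the last covered coordinate are missing from these shares, and the gap falls unequally on the subgenomes. Every A and B chromosome stopped near the limit, as did 2D, 3D, 5D and 7D, but 1D, 4D and 6D ended before it. The shares therefore do not compare whole subgenomes.

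By the number of TSRs that hold 50% of the tags off the organelles, shoots concentrated their transcription starts on fewer regions than roots did. These tags include those in no TSR, and in every species a smaller share of root tags than of shoot tags lay in TSRs. In wheat that share was 70.7% and 70.6% in root and 78.2% and 78.5% in shoot. This raises the root numbers, by an amount that was not measured. Sorghum and wheat had no sequence named as an organelle, so no tags were left out there. Whether organelle tags lie on other sequences of these species was not tested. In maize 997 and 1314 TSRs held 50% of the tags of the shoot libraries, and 2766 and 2788 those of the root libraries. In sorghum the numbers were 633 and 754 in shoot and 2149 and 2676 in root. Wheat roots had the highest numbers, with 7600 and 8687 TSRs against 1457 and 1746 in shoot, and rice had 473 and 427 in shoot and 611 and 1721 in root. The rice difference was 716 TSRs, 161 without root replicate 2 and 1271 without root replicate 1. In the number of TSRs every root library lay above every shoot library of its species, a split that chance gives with an exact two-sided permutation p of 0.333. The 10 most used TSRs also took a larger share of tags in every shoot library than in every root library of maize, sorghum and wheat, but in rice they took 17.6% and 18.6% in shoot and 19.4% and 13.7% in root. Few TSRs lacked any tag in the other tissue, a strict criterion that a single tag fails. It says little about large differences: in maize 25741 TSRs were called with a change of at least 4-fold. Of TSRs with a mean of at least 1 CPM in the tissue, 925 of 39833 in maize shoot and 601 of 45173 in maize root had no tag in the other tissue. Sorghum had 607 such TSRs in shoot and 384 in root, wheat 1522 and 2065, and rice 640 and 1037. With a floor of 3 counts over both libraries, absence at 1 CPM means at least 24.3-fold higher in maize shoot and at least 18.3-fold higher in maize root.

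**Figure D3:**
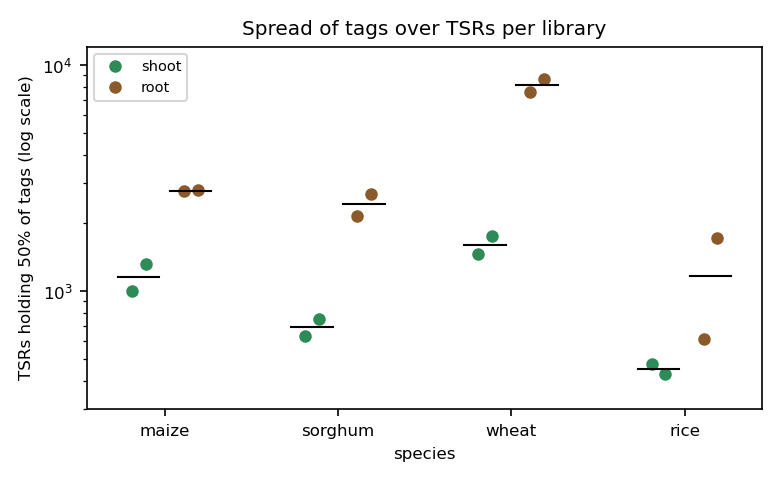
Number of TSRs that together hold 50% of the tags off the organelles in each library (log scale), by species and tissue. Points are libraries and lines are means of 2. Root libraries ran from 611 in rice to 8687 in wheat and shoot libraries from 427 in rice to 1746 in wheat. Sorghum and wheat had no sequence named as an organelle, so all their tags are included.

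The width of start regions differed little between root and shoot once the same TSRs were compared. With 50 tags drawn from each TSR, 45.9% ± 0.288 of the 15443 maize TSRs with at least 50 tags in all 4 libraries were narrow in shoot and 45.9% ± 0.0916 in root (SD, n = 2), narrow meaning that the 10% and 90% quantiles of tags lay within 10 bp. In sorghum the shares were 51.8% ± 0.00754 and 51.7% ± 0.00754, in wheat 64.2% ± 0.151 and 63.9% ± 0.394, and in rice 60.1% ± 0.116 and 59.9% ± 0.105. Both root libraries lay below both shoot libraries in sorghum and rice, and the libraries overlapped in maize and wheat. The mean width of these TSRs was larger in both root libraries than in both shoot libraries of each species, for example 31.2 and 31.3 bp against 30.7 and 30.5 bp in maize. When each library used its own TSRs of at least 50 tags, 59.1% ± 2.30 were narrow in rice shoot and 70.1% ± 1.21 in rice root, with an exact permutation p of 0.333 (two-sided). In wheat the share was 73.8% in shoot replicate 1, 58.5% in shoot replicate 2 and 61.4% and 60.9% in root. Maize and sorghum libraries overlapped between the tissues, at 47.9% to 58.5% and 52.2% to 64.2%. The minimum of 50 tags is a raw count, so the number of TSRs it admits differs between libraries. It was 26859 and 17489 in rice shoot and 31734 and 44088 in rice root. Within each tissue except wheat shoot, the library with more such TSRs had the larger narrow share. The rice difference therefore does not separate the tissue from the number of TSRs admitted. The difference changed sign between the 2 ways of choosing TSRs in rice, from 11 to -0.235 percentage points, in sorghum, from 5.86 to -0.123, and in maize, from 4.13 to -0.0615.

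Start sites moved within TSRs between the tissues slightly more often than between replicates. In maize the most used base differed by more than 5 bp in 12.2% of 15443 TSRs between replicates and in 13.4% to 13.7% between root and shoot. In sorghum it differed in 10.8% and 11.2% of 18761 TSRs between replicates and in 12.6% to 12.9% between tissues. In wheat the ranges were 7.60% to 7.85% and 8.31% to 8.96% of 11669 TSRs, and in rice 8.18% to 8.77% and 10.1% to 10.5% of 12783. All 4 pairs between tissues lay above both pairs within tissues in each species. The mean tag position differed in 517 maize, 691 sorghum, 16 wheat and 407 rice TSRs (limma, adjusted p under 0.05), by a median of 6.98, 7.99, 2.84 and 7.07 bp, with shifts in both directions: 293 of the maize TSRs started farther downstream in root and 224 farther upstream. Leaving out any single library, or taking the replicate number as a block, left 0 calls in every species, while 2315 to 3402 maize, 2776 to 3751 sorghum, 1327 to 2252 wheat and 2130 to 2315 rice TSRs had an unadjusted limma p under 0.05. With at least 100 tags the calls rose to 870, 1066 and 43 in maize, sorghum and wheat.

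**Figure D4:**
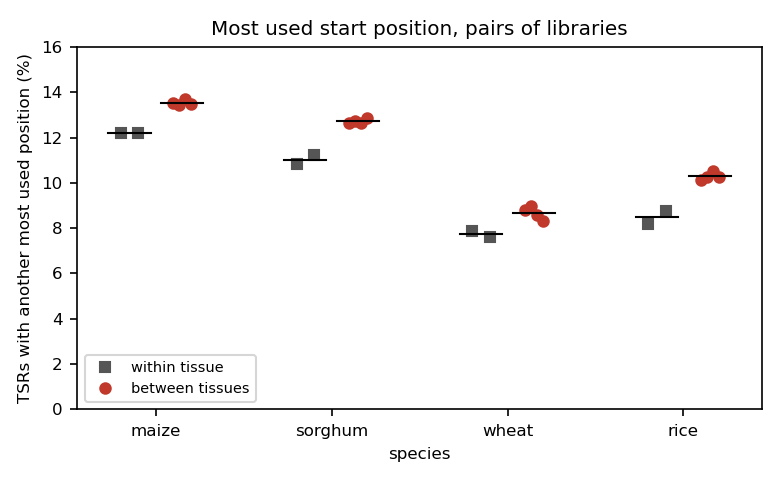
Share of TSRs (percent) whose most used base differs by more than 5 bp between the libraries of a pair, by species. Squares are the 2 pairs of replicates, circles the 4 pairs of root and shoot, and lines their means. The circles lie above the squares in each species, for example 13.4% to 13.7% above 12.2% in maize.

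TSRs had an opposite-strand neighbour upstream less often than strand labels drawn at random would give. An opposite-strand TSR lay within 500 bp upstream for 26.5% of maize TSRs, against 34.6% ± 0.0762 over 100 shuffles of the strand labels. The shares were 42.4% against 47.1% ± 0.0728 in sorghum, 13.4% against 23% ± 0.0632 in wheat and 43.6% against 46.9% ± 0.0685 in rice. Among TSRs with a mean of at least 1 CPM, 9.39% in maize, 10.2% in sorghum, 6.55% in wheat and 9.43% in rice had such a neighbour, against 20.8%, 19.99%, 14.9% and 18.4% after shuffling. In every species the share lay below the lowest of the 100 shuffles, in both sets. Shuffling also breaks up runs of TSRs on one strand, so the comparison does not separate a shortage of divergent pairs from clustering on a strand.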

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

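Of the tests in this part, the one of a coordinate limit in wheat was written down before its result was seen, and all the others were chosen after the results had been seen.

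Isolated TSRs, which stand alone on their strand, numbered 73 in maize, 70 in sorghum, 131 in wheat and 69 in rice and held from 8.06% to 22.9% of the tags of a library. Their share was lower in every root library than in every shoot library of maize (by -4.46 percentage points), sorghum (-6.23) and wheat (-7.04) and higher in rice (4.50), a difference between species that was not tested; the wheat difference rested on shoot replicate 1, which held 21.2% where shoot replicate 2 held 10.5%, and was -1.69 without the former and -12.4 without the latter. The sorghum difference rested on the isolated TSR at position 54133784 of chromosome 3, without which it turned to 1.28 with the libraries of the tissues overlapping, and that of maize was -2.68 without the TSR at position 222780404 of chromosome 2. Amplification of single molecules in one library is argued against for the set, though not for each member, by replicates, which differed by a median under 2-fold in 7 of 8 tissues (the exception is wheat shoot, with a median log2 ratio of 1.69), while a rice TSR at position 13727009 of chromosome 12 (plus strand) had 9158 CPM in root replicate 1 and 0.105 CPM in root replicate 2. Transcripts that each follow the tissue in their own way are argued against for the set as a whole, though not for members such as that sorghum TSR (-5.43) or the wheat TSR at position 506480989 of chromosome 4B (-11.89), by log2 fold changes spread less widely than those of other TSRs of at least 100 CPM in 3 of 4 species, with an interquartile range of 0.40 against 1.71 in sorghum, 0.33 against 2.01 in wheat and 0.42 against 3.96 in rice (one-sided permutation p of 0.0001 each, the smallest that 10000 permutations can give). One source of tags that changes as a whole between libraries may account for isolated TSRs in the 3 species where their range was under 0.5 times that of the others. TSRs that hardly change between the tissues would also give a narrow range, and this test cannot tell the 2 apart. The median log2 fold change of isolated TSRs was -0.12 in sorghum, -0.07 in rice and -1.49 in wheat. In maize the test does not point to one source, with a range of 1.09 against 1.28 (permutation p = 0.201). There 47 of 73 isolated and 748 of 1004 other such TSRs differed between the tissues. Each of these permutation tests treats TSRs measured in the same libraries as independent. What such a source is was not tested, and a response of the whole set to the tissue stays open.

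Shoot replicate 1 of wheat stood apart from shoot replicate 2, with a correlation of 0.810 where the root replicates had 0.983. A root library under a shoot label is argued against, since the highest correlation of this library with a root library was 0.619, and so is lower depth, since the shoot pair still correlated at 0.809 and the root pair at 0.982 with all 4 libraries thinned to one total. More tags in isolated TSRs went with that library, since the 108 TSRs that are isolated in root had a median log2 ratio of shoot replicate 1 over 2 of 1.60 and the 819 other TSRs of at least 100 CPM in root had -0.57. As the whole reason for the low correlation they are argued against too, because with isolated TSRs left out the shoot pair correlated at 0.804 and the root pair at 0.983. What sets the library apart stays open, and no biological explanation was tested, because both libraries carry the same label.

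Wheat positions stopped near one coordinate on most sequences: 18 of 22 ended within 100000 bp of position 536870912, which is 2 to the power of 29. The ends of the sequences themselves are argued against, since 17 of the 22 last positions lay within 100000 bp of each other. A coordinate limit in a processing step before deposit is a candidate explanation that passed its written test. The 18 sequences at the limit are the pattern itself, so that part of the test could not fail. Only the strand part could have gone against it. The few tags beyond the limit, 2 in all, lay on the minus strand, where the 5′ end is the far end of a read. One of them lay 24 bp past the limit and the other 83946 bp, which a read that begins before the limit reaches only across a gap of about that size. With 2 such tags the strand part of the test is weak, and which step set the limit was not tested.

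The tag-weighted share of narrow TSRs moved in opposite directions between the tissues of different species: root minus shoot was -1.64 percentage points in maize, 4.39 in sorghum and -10.5 in wheat, with every root library on one side of every shoot library, and the difference between species was not tested. In rice it was -0.528, with the libraries of the tissues overlapping, and ran from -6.62 without shoot replicate 1 to 5.56 without shoot replicate 2. Without thinning to 50 tags it was -4.61 in rice, with both root libraries below both shoot libraries. With isolated TSRs left out the maize value turned to 0.703, so its direction rests on them, that of sorghum went to 6.94 and that of rice to -8.65. The maize value was -3.58 with positions joined at 50 bp and -2.49 with a width limit of 20 bp. With at least 100 tags per TSR the maize libraries of the tissues overlapped. Leaving out 1 library gave -2.49 to -0.797 in maize, where the low end is without root replicate 2 and the high end without root replicate 1. In sorghum it gave 1.85 without root replicate 2 and 6.94 without root replicate 1, and in wheat -4.96 without shoot replicate 1 and -15.9 without shoot replicate 2.

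Some single bases held a large share of the tags of a library and lay in no TSR, because no other library had more than 2 tags there, so they entered no test of TSRs. Their tags stay in the library totals and in the shares by sequence class. In maize these were position 106400913 of chromosome 7 (minus strand) with 0.523% of the tags of shoot replicate 1, position 2940971 of chromosome 3 (plus strand) with 0.279% of shoot replicate 2, and 2 positions in root replicate 2, 81014879 of chromosome 10 (plus strand) with 0.231% and 27809812 of chromosome 5 (minus strand) with 0.267%. In sorghum, position 57019965 of chromosome 6 (plus strand) held 0.282% of root replicate 1. In wheat, position 333519304 of chromosome 7A (minus strand) held 1.66% of root replicate 1, which is 544640 tags against 0 in the other libraries of the species, and without it the root minus shoot difference of subgenome A was 1.56 percentage points instead of 2.15. In rice, positions 2188188 of chromosome 6 and 17809467 of chromosome 9, both on the minus strand, held 0.294% and 0.333% of shoot replicate 2, and position 16285788 of chromosome 7 (plus strand) held 1.008% of root replicate 2. All 9 hold at least 0.2% of a library, above the limit of 3 tags that a count of 0 allows. A limit of 0.1% gave 18 such positions.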

How the results depend on the processing

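Start zones, isolated TSRs left out, crossed pairing, TSRs shared by all libraries, the opposite-strand minimum of 1 CPM, positions high in 1 library or a single isolated TSR left out and the leaving out of libraries for results other than the root and shoot test were chosen after seeing the data. All other alternatives were set before the data were examined. The causes of the changes below were not tested, except where fewer features, fewer libraries or larger units tested are part of the alternative itself. Of the counts of TSRs that differ between tissues, 46 alternatives stayed within 1.5 times and 17 did not. For the TSRs given by position, 471 values kept direction and call, 7 newly passed the threshold and 5 turned. Start zones brought several of the values that kept direction closer to no change, for example 2 maize values from 9.93 to 2.25 and from -10.55 to -3.41.

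Calls moved under a filter of 1 CPM in 2 libraries, to 28562 in maize, 25719 in sorghum, 14446 in wheat and 28061 in rice, and with start zones, to 29510, 23929, 13714 and 29685. With no filter sorghum had 83956 and wheat 59365. DESeq2 called 35554 TSRs in sorghum, and library size alone gave 118607 in rice. Leaving out 1 library gave 39073 to 44896 calls in maize, 24347 to 49372 in sorghum, 1287 to 136718 in wheat and 42573 to 59476 in rice, with a lone library of a tissue assumed to vary like the other tissue. Same-numbered libraries share only a number: their deviations correlated at -0.09 in maize, -0.10 in sorghum, -0.18 in wheat and -0.05 in rice. The replicate block gave 47543, 52248, 20863 and 57164 calls. Crossed pairing gave 22829 calls in wheat.

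The sorghum TSR at position 43407652 of chromosome 10 had a log2 fold change of -0.05, which turned to 0.51 with library size alone, 0.0074 with the replicate block, and ran from -0.47 without shoot replicate 2 to 0.45 without shoot replicate 1 and 0.12 without root replicate 1. The rice TSR at position 8912 of chromosome 9 turned from 0.52 to -0.010 without root replicate 1 and was 0.98 without root replicate 2. The share of tags in isolated TSRs in sorghum turned from -6.23 to 1.28 points with its most influential TSR left out. The tag-weighted narrow share in maize turned from -1.64 to 0.703 points with isolated TSRs left out. On shared TSRs the narrow share, root minus shoot, turned to -0.0615 percentage points in maize, -0.123 in sorghum and -0.235 in rice.

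The mean position test (limma) gave 0 calls with the replicate block in all 4 species, with 2900, 3438, 1590 and 2280 TSRs at an unadjusted p under 0.05, and 0 without any 1 library. With at least 100 tags it gave 870, 1066, 43 and 571 calls. The excess of moved start bases between tissues was 2.33 points in maize, 2.55 in sorghum and 2.48 in rice with at least 100 tags, and 1.26 to 1.41 in maize, 1.46 to 1.99 in sorghum, 0.788 to 1.28 in wheat and 1.43 to 2.14 in rice without 1 library.

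The gap in correlation was 0.206, 0.184 and 0.251 with log2(CPM + 0.1) in maize, sorghum and rice, and 0.769, 0.776, 0.785 and 0.764 in the 4 species for TSRs of at least 10 CPM. Without 1 library it ran from 0.171 to 0.189 in maize, 0.166 to 0.177 in sorghum, 0.123 to 0.368 in wheat and 0.210 to 0.223 in rice. The chloroplast difference was -0.886 points in maize and -1.58 in rice with positions of at least 3 tags, and -0.297 and -0.267 by positions. The mitochondrial difference was 0.663 and 1.08, and 0.0552 and 0.237. Subgenome A had 1.56 points without the wheat position that holds at least 0.2% of 1 library. By positions, subgenome A had -0.0260 and subgenome B -0.275. The opposite-strand share stayed below the shuffled share at 200, 500 and 1000 bp, at 1 CPM and without any 1 library.

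The alternatives for genes, gene lists and sequence around start sites were not run, for lack of an annotation. Depth limits what can be said of starts of low use: 71.2% to 79.3% of the positions of a library held a single tag.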

Other observations

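The use of start regions within a start zone also differed between the tissues, which no comparison above covers. Among zones with at least 2 TSRs of 1 CPM or more, the share of tags per TSR changed in 2094 of 8206 zones in maize, 2978 of 8280 in sorghum, 292 of 6519 in wheat and 3517 of 7278 in rice (edgeR diffSpliceDGE, adjusted p under 0.05). In 156, 238, 24 and 347 of these zones a TSR was higher in root and another higher in shoot, each by at least 2-fold, on the same strand. On maize chromosome 9 (minus strand), a TSR at position 104333456 averaged 11.2 ± 0.789 CPM in root and 0 CPM in shoot (SD, n = 2), while a TSR at position 104331051, 2405 bp downstream, averaged 0.070 ± 0.069 CPM in root and 69.4 ± 3.16 CPM in shoot. On sorghum chromosome 1 (plus strand), the TSR at position 72142795 averaged 197 ± 29.9 CPM in root and 1.83 ± 0.293 CPM in shoot, and one 3214 bp downstream, at position 72146009, 0.183 ± 0.0154 and 20.5 ± 1.53 CPM.

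In wheat, the TSR at position 254529074 of chromosome 1D (minus strand) averaged 189 ± 4.48 CPM in root and 6.24 ± 4.60 CPM in shoot, and one 773 bp upstream, at position 254529847, 1.33 ± 0.104 and 22.4 ± 8.76 CPM. In rice, the TSR at position 5633974 of chromosome 12 (plus strand) averaged 15929 ± 2508 CPM in shoot and 1818 ± 257 CPM in root, while a small TSR at position 5634727, 753 bp downstream, averaged 0.531 ± 0.0405 and 15.5 ± 0.315 CPM. In each species this is the zone with the largest opposite changes at 10 CPM or more, judged by the smaller of its changes, and it was chosen after its values were seen. In wheat the test recovered 0% of simulated 4-fold changes. The zones of all 4 species were not counted again with single libraries left out.

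A hypothesis written before its result was seen held that TSRs that differ at least 4-fold between tissues are narrower than TSRs that differ less than 2-fold, at the same level. The test argued against it as a rule for these plants: in 3 of 4 species the median width of the TSRs differing 4-fold was equal to or above that of the others. It was 7 and 7 bp in maize, 7 and 4 bp in sorghum and 7 and 3 bp in rice, and 6 and 11 bp in wheat. Within 10 bins of the level, the mean difference in log2 width was -0.11 in maize, 0.25 in sorghum, -0.60 in wheat and 0.58 in rice (permutation p of 0.001 each, two-sided, the smallest that 1000 permutations can give). The median was narrower in 10 bins of wheat, wider in 7 of sorghum and 8 of rice, and in maize narrower in 3 and wider in 3. These differences at equal level, which went both ways between species, were used first to judge the hypothesis and could not tell. The plain medians, which the written prediction names, were made to decide after both sets of values had been seen, so the verdict rests on that choice.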
